A study of Homo sapiens with 4 samples.

How the data were processed

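Binding of MITF, the basic helix-loop-helix leucine zipper factor that controls the melanocyte lineage, was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in 4 libraries, 1 per condition. Primary human melanocytes received a lentivirus for red fluorescent protein (RFP, the control) or for BRAFV600E, the constitutively active form of the kinase BRAF, for 48 hours. Cells of the melanoma line COLO829 received the solvent DMSO or PLX4032 (vemurafenib), an inhibitor of mutant BRAF, for 24 hours. The labels give BRAF signaling as ON in the BRAFV600E and DMSO libraries and as OFF in the RFP and PLX4032 libraries. Chromatin was cross-linked, sonicated and precipitated with an antibody to MITF, and single 50 bp reads were sequenced, per the labels' protocols.

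The deposited data used here are 1 list of peak intervals with a chromosome, a start and a stop in bp on build hg19, per the file headers. The list is described there as the MITF peaks found in both the primary melanocytes and COLO829. Per the submitters' processing notes, Bowtie and SAMtools were used, with no version given. The peak caller, its threshold, the control library, the overlap required between cell types, and whether the libraries of a cell type were pooled are not given in the sources used here. The file has 0 columns for single libraries, so it holds no height, fold, p-value or read count, and the depth of the libraries is unknown. Positions are printed as the authors' file gives them.

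Each of the planned comparisons (BRAFV600E against RFP, PLX4032 against DMSO, BRAF signaling ON against OFF, and COLO829 against melanocytes) needs a value or a peak call per library, so none of them was analysed here. A peak whose occupancy differs by condition and a peak that does not cannot be told apart in this list. The 15 gene lists, motif counts and promoter, exon and intron shares fixed before the data were examined need gene names, an annotation or sequence on hg19. The gene table at hand is on GRCh38.p14, another build, and was not used, so peaks are named by position. The planned rule for naming peaks ranked them by a value per library or by the authors' score. With neither in the file, the regions named here were chosen by rules set after the file was seen: the 10 widest peaks, the 12 windows of 1 Mb with the most peaks and the 10 groups with the most peaks.

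From the 16745 rows, 8 outside chromosomes 1 to 22 and X were left out. The remaining 16737 rows held 16564 distinct intervals, which were counted once each. Peak density was the number of peaks divided by the span from the first to the last peak of a chromosome, with exact 95% Poisson intervals that cover counting error only. A pair of peaks was called near when their centres lay within 10 kb, and groups were runs of at least 4 peaks with gaps under 10 kb. Observed spacing was compared with 1000 random placements that kept the number and the widths of the peaks and allowed no overlap, either over the span of each chromosome or within bins of 1 Mb or 5 Mb. A one-sided permutation p was the share of placements with a value as high, and the smallest it can take is 0.001. Width comparisons used permutation tests with 100000 draws. Peaks are not biological replicates, so these p-values describe the arrangement of this list and not variation between cultures. In 5 simulated sets of 16564 uniformly placed peaks, the ratio of observed to random near shares averaged 0.99 over whole chromosomes (range 0.94 to 1.02). With 10% of peaks moved beside another peak it averaged 2.61 (range 2.58 to 2.64).

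The alternatives set before the data were examined that could be applied were merging of peaks less than 500 bp apart and restriction to chromosomes 1 to 22. The other alternatives set beforehand concern values per library, an authors' score or an hg19 annotation and could not be applied, and a value per kb of peak does not exist without values. Further alternatives were chosen after seeing the data: other distances, other bins for random placement, repeats counted, and the rows that follow the sorted list left out. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.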

Results

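MITF occupancy was profiled by ChIP-seq in 4 libraries that combine 2 cell types with 2 states of BRAF signaling. The design asked how MITF binding changes with oncogenic BRAF, in primary melanocytes given BRAFV600E or an RFP control and in COLO829 melanoma cells given PLX4032 or DMSO. The deposited list gives the positions of peaks described as present in both cell types, with no value for a single library. The effect of BRAFV600E, the effect of PLX4032 and the difference between the cell types were therefore not analysed here, and the following values describe the shared set of binding regions. Library depths are unknown, and with 1 library per condition there was no replicate error.

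The shared set comprised 16564 distinct MITF peaks on chromosomes 1 to 22 and X of hg19, and together they covered 15.6 Mb. None of the distinct peaks overlapped another. The median width was 868 bp, with quartiles of 650 and 1137 bp and a range of 251 to 4384 bp. Peaks wider than 2000 bp numbered 347, or 2.09% of the set. The widest peak lay near the start of chromosome 18 (107235 to 111619, 4384 bp). The next widest were on chromosome 6 (58776038 to 58780033, 3995 bp), chromosome 19 (27731801 to 27735689, 3888 bp) and chromosome 7 (61966997 to 61970832, 3835 bp). Each of these 3 peaks bordered the longest stretch without peaks on its chromosome, which measured 5.50, 3.55 and 5.79 Mb respectively. With no read values and no control library given, whether the widest intervals reflect MITF binding was not tested. The other 6 of the 10 widest peaks had another peak centred within 30 kb. This is common among wide peaks: for peaks from 1219 bp, the median distance to the nearest peak was 29758 bp. These 6 peaks lay on chromosome 19 (1168308 to 1172026), chromosome 6 (10411103 to 10414689), chromosome 11 (65187223 to 65190771), chromosome 9 (73032899 to 73036404), chromosome 10 (102756069 to 102759545) and chromosome 7 (5463289 to 5466713).

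**Figure D1:**
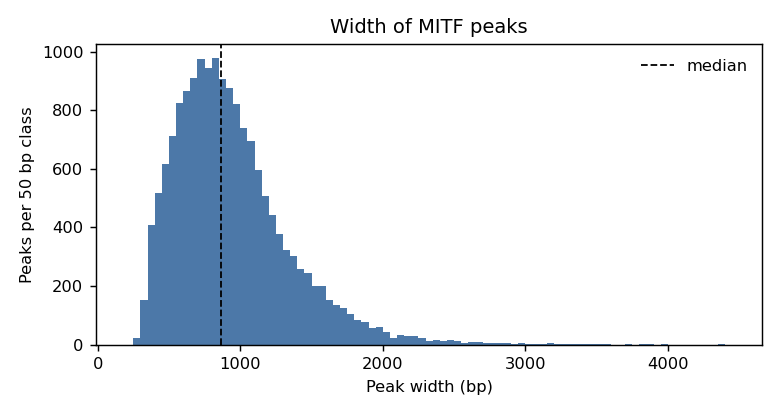
Histogram of the widths of the 16564 distinct MITF peaks, in bp on the x axis and peaks per 50 bp class on the y axis. The dashed line marks the median of 868 bp, and the tail to the right reaches 4384 bp.

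MITF peaks were densest on chromosomes 19, 22 and 17, which are among the most gene-rich human chromosomes, and sparsest on chromosomes X, 18 and 4. Chromosome 19 carried 717 peaks, or 12.2 peaks per Mb of span (95% interval 11.3 to 13.1). Chromosome 22 had 11.7 peaks per Mb (10.6 to 12.9) and chromosome 17 had 10.4 (9.70 to 11.1). Chromosome 20 followed with 8.80 peaks per Mb (8.08 to 9.57). At the other end, chromosome X had 2.44 peaks per Mb (2.20 to 2.70), chromosome 18 had 3.85 (3.43 to 4.31) and chromosome 4 had 3.86 (3.58 to 4.15). The density over all chromosomes was 5.65 peaks per Mb. The interval lay above that value on 8 chromosomes and below it on 7, and it included the value on the remaining 8. Peaks were unevenly spread along the chromosomes, so intervals for counting error are too narrow to make this sorting a test. The highest and lowest densities differed 4.995-fold, and 3.17-fold among chromosomes 1 to 22, where chromosome 18 was lowest, nearly level with chromosome 4. With the longest stretch without peaks taken out of each span, chromosome 4 (3.96 peaks per Mb) was lower than chromosome 18 (4.10). Chromosome 9 then rose from 5.30 to 6.30 peaks per Mb. Chromosome 1 carried the most peaks, 1574, at a density of 6.34 per Mb (6.03 to 6.66). The number of DNA copies of each chromosome in these cells, which can affect how readily a peak is called, was not used here.

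**Figure D2:**
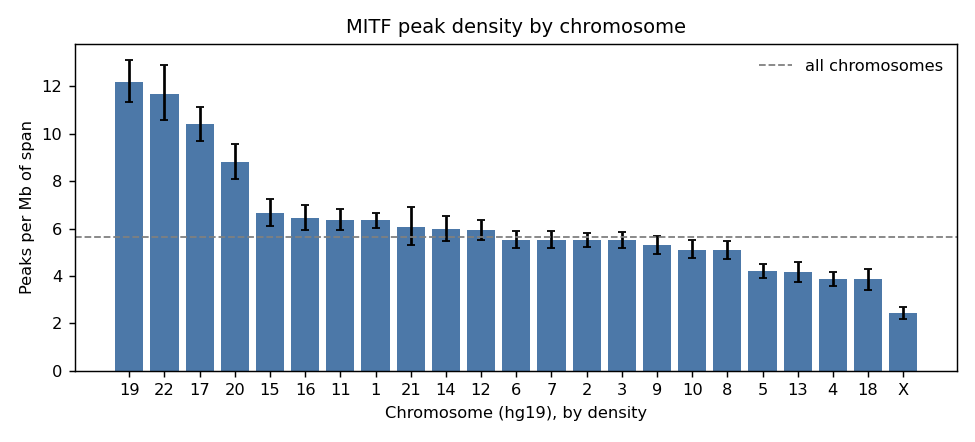
MITF peaks per Mb of span for each chromosome, ordered by density; bars start at 0 and error bars are exact 95% Poisson intervals for counting error. Chromosomes 19, 22 and 17 exceed 10 peaks per Mb, and the dashed line marks the 5.65 peaks per Mb of all chromosomes together.

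Chromosomes with more peaks per Mb also had wider peaks and a larger share of peaks with a near neighbour. The median width was 1013 bp on chromosome 22 and 986 bp on chromosome 19, against 722.5 bp on chromosome 18 and 727 bp on chromosome 5. Across the 23 chromosomes, density and median width were correlated (Pearson's r = 0.76, permutation p = 3e-05; Spearman's rho = 0.66, permutation p = 0.00085). Density and the share of peaks with a neighbour within 10 kb were correlated as well (r = 0.80, permutation p = 3e-05; rho = 0.71, permutation p = 0.00022). These 2 relations formed the family, and the Benjamini-Hochberg adjusted values were 3e-05 for both r, and 0.00085 and 0.00044 for the rho of width and of near neighbours. Without chromosomes 19 and 22, which lie farthest from the median density, r was 0.62 for width and 0.68 for near neighbours. A higher density by itself brings neighbours closer together, so the second relation is partly built in. Chromosome 16 had the highest share of near neighbours, 22.5%, at 6.43 peaks per Mb. Its span includes a stretch of 12.8 Mb without peaks, and without that stretch its density was 7.49 peaks per Mb.

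Along the chromosomes, MITF peaks were spread less evenly over 1 Mb windows than in random placement, with more windows of many peaks and more windows without any. The most populated 1 Mb window was on chromosome 17 (79000001 to 80000000) and held 31 peaks. It was followed by windows with 29 peaks on chromosome 7 (100000001 to 101000000) and on chromosome 16 (30000001 to 31000000). Windows with 28 peaks lay on chromosome 16 (2000001 to 3000000) and chromosome 19 (47000001 to 48000000). A window on chromosome 9 (130000001 to 131000000) held 27 peaks and one on chromosome 11 (65000001 to 66000000) held 26. Windows with 25 peaks lay on chromosome 1 (156000001 to 157000000), chromosome 12 (56000001 to 57000000), chromosome 22 (41000001 to 42000000) and at 2 places on chromosome 19 (2000001 to 3000000 and 4000001 to 5000000). The median window held 4 peaks.

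In total, 34 windows held more peaks than any window of the same chromosome in 1000 random placements, and these windows contained 754 peaks. Against the highest value of any chromosome in those placements, 30 peaks, 1 window was above, with 0.187% of all peaks. Of the 34 windows above the maximum of their own chromosome, chromosomes 1 and 9 had 5 each and chromosome 6 had 4. The window on chromosome 17 was above the highest random value for its chromosome, 26, whereas the windows on chromosomes 19 and 22 with 25 or 28 peaks were not above theirs, 30 and 29. The variance of the peak number per window was 4.76 times its mean, against at most 1.69 in the random placements. Of the 2956 windows, 464 (15.7%) held no peak, compared with at most 1.86% in the random placements. Those placements could fall anywhere in the span of a chromosome, also in sequence that cannot hold peaks. Such sequence was not taken out here, so it may add to both contrasts. It can also lower the random maxima, so it may add to the 34 windows as well. Chromosomes 1 and 9, with 5 such windows each, also held the 2 longest stretches without peaks (22.5 and 22.4 Mb). Some of the 34 windows were only just above their maximum, such as 21 peaks against 20 on chromosome 1.

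**Figure D3:**
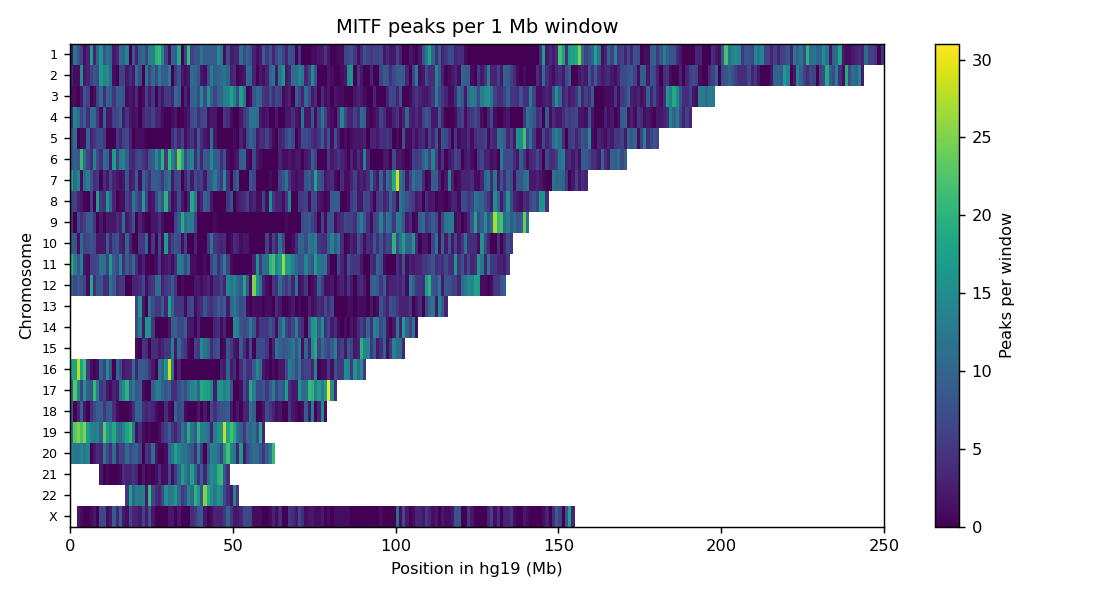
Number of MITF peaks in each 1 Mb window, by colour, with position in Mb of hg19 on the x axis and chromosomes 1 to 22 and X on the y axis; white lies outside the span from first to last peak. The brightest window, with 31 peaks, lies near the end of chromosome 17, and dark stretches on chromosomes 1 and 9 are the 2 longest without peaks.

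The longest stretches without a peak were on chromosome 1 (121485595 to 144009690, 22.5 Mb), chromosome 9 (44070951 to 66457868, 22.4 Mb) and chromosome 16 (33964330 to 46722417, 12.8 Mb). Chromosome X had a stretch of 10.8 Mb (85152962 to 95939085) and chromosome 5 one of 8.63 Mb (22506362 to 31133656). In all, 88 stretches of at least 2.5 Mb held no peak, and they added up to 383 Mb. Assembly gaps and sequence to which short reads cannot be mapped were not located here, so a stretch without peaks does not show that MITF was absent. Peaks not found in both cell types are not listed either, so such a stretch may hold peaks of a single cell type.

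Neighbouring MITF peaks were separated by a median gap of 69021 bp, with quartiles of 26739 and 163919 bp. Of the 16564 peaks, 2478 (14.96%) had another peak centred within 10 kb. Random placement over whole chromosomes gave a mean of 10.7% and at most 11.8% in 1000 placements, so the observed share was 1.40 times the random mean (permutation p = 0.001, the smallest that 1000 placements can give). When the number of peaks in each 1 Mb bin was kept, random placement gave a mean of 15.6%, with a range of 14.6% to 16.8%. The observed share lay inside that range but near its low end, with 34 of the 1000 placements as low. Within 25 kb the observed share was 38.7%, above the highest of the placements within 1 Mb bins, 36.5% (permutation p = 0.001, likewise the smallest possible). The excess was not even over distance. Pairs of neighbouring peaks with centres 1.5 to 5 kb apart numbered 221, against 474 to 610 in those placements, whereas pairs 5 to 10 kb apart numbered 935, against 640 to 828.

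**Figure D4:**
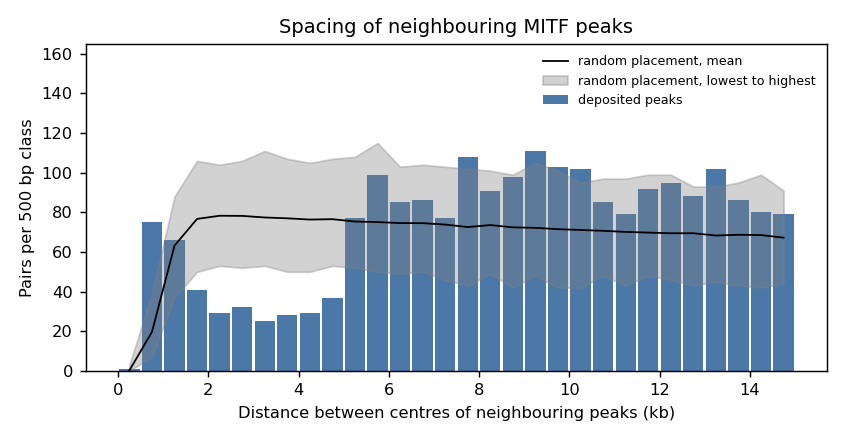
Number of neighbouring peak pairs per 500 bp class of centre distance, up to 15 kb on the x axis; bars are the deposited peaks, the line is the mean and the grey band the lowest to highest of 1000 random placements within 1 Mb bins. Bars between 1.5 and 5 kb lie below the band, and the number steps up at 5 kb, from 37 pairs in the class below to 77 in the class above.

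Most peaks of this shared list stood alone at this scale, and the largest groups had 5 members. Peaks not found in both cell types are not listed, so gaps, neighbours and groups here are those of shared peaks only. With gaps under 10 kb, 13755 peaks were single, 1180 pairs and 122 triplets were formed, and 20 groups had 4 or more peaks, 83 peaks in all. The 3 groups of 5 peaks lay on chromosome 2 (70335381 to 70370272), chromosome 19 (3548319 to 3574670) and chromosome 16 (2954001 to 2985093). Among the groups of 4, those with the most bp in peaks were on chromosome 1 (157962741 to 157990022, 7062 bp in peaks) and chromosome 3 (134076186 to 134094209, 6235 bp in peaks). The next 5 lay on chromosome 7 (5594162 to 5610544), at 2 further places on chromosome 1 (31270829 to 31297425 and 235105386 to 235133925) and at 2 places on chromosome 17 (74557949 to 74582634 and 38254972 to 38268500). Random placement over whole chromosomes gave at most 12 such groups. Placement within 1 Mb bins gave a mean of 18.1 and at most 31, so the number of groups did not exceed what the density of each 1 Mb bin gives.

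Wider peaks had nearer neighbours over the whole set. Peaks were divided into 5 classes of about equal size by width. In the narrowest class, up to 603 bp, the nearest peak was at a median distance of 47118 bp, and 11.96% (Wilson 95% interval 10.9% to 13.1%) had a neighbour within 10 kb. In the widest class, from 1219 bp, the median distance was 29758 bp and 16.6% (15.3% to 17.9%) had such a neighbour. Across peaks, which are not independent replicates, Spearman's rho between width and distance to the nearest peak was -0.13. Ranked within 1 Mb bins that held at least 4 peaks, rho was -0.010, inside the range of 1000 shuffles of the widths within bins, the lowest of which was -0.016.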

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

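Of 27 values recomputed for 6 results, 18 stayed close to the reported value: counts, shares and density ratios within 1.5 times, ratios to random placement within 10% or, for the median width, within 1 SD of the widths. Merging peaks less than 500 bp apart left 16425 peaks with a median width of 873 bp and gave a near-neighbour ratio to random placement of 1.27. Restriction to chromosomes 1 to 22 lowered the ratio of highest to lowest chromosome density from 4.995 to 3.17, because chromosome X is the lowest. The other alternatives named here were chosen after seeing the data. The share of peaks with a near neighbour was 4.36% for a distance of 5 kb and 38.7% for 25 kb, as a shorter or longer distance must give fewer or more. The number of groups of at least 4 peaks was 74 with gaps under 15 kb and 0 with gaps under 5 kb, so the groups depend on the gap allowed. The ratio of the near share to random placement, 1.40 over whole chromosomes, was 1.12 within 5 Mb bins, 1.18 with intervals less than 2 kb apart merged, 1.25 with stretches of at least 2.5 Mb without peaks taken out, and 0.96 within 1 Mb bins. With the density of each 1 Mb bin kept, the share within 10 kb, 14.96%, lay inside the random range of 14.6% to 16.8%, but it pools a deficit of pairs 1.5 to 5 kb apart with an excess of pairs 5 to 10 kb apart (935, random maximum 828), and the share within 25 kb stayed above all placements (highest 36.5%). No paired analysis was possible because each condition had 1 library and the list gives no value per library. The depth of the libraries is unknown, so how many weaker shared peaks were missed cannot be stated.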

Other observations

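The tests on repeated entries and on spacing were chosen after the list had been seen, except 2 that were set before their values were computed: the step at 5 kb in narrow and in wide pairs, and the distance from repeated intervals to their neighbours. No biological explanation was tested for these patterns. No annotation or sequence on hg19 was at hand, and the list does not separate the groups of the design.

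Neighbouring MITF peaks were scarce at centre distances of 1.5 to 5 kb, with 221 such pairs against a mean of 540 and a lowest value of 474 in 1000 random placements within 1 Mb bins, a ratio of 0.41. Pairs with centres less than 1.5 kb apart numbered 142, 1.71 times the random mean and above the highest placement of 110, which argues against close calls fused into one interval, but the excess lay in nearly abutting intervals 500 to 1000 bp apart (75 pairs, random maximum 39) and not at 1000 to 1500 bp (66 pairs, random range 37 to 88). The number rose in a step at 5 kb, from 66 pairs 4 to 5 kb apart to 176 pairs 5 to 6 kb apart, and this ratio was 2.83 (95% interval 1.85 to 4.45, exact) in the narrower pairs, up to the median mean width of 894 bp, and 2.53 (1.70 to 3.83) in the wider pairs. A rise between the same classes in narrower and wider pairs could come from a local background taken over 10 kb around each peak's centre. Some peak callers use such a background, and a strong peak could then hide weaker ones within 5 kb. These classes are too coarse to tell a step fixed in centre distance from a step that shifts with peak width. The 5 kb edge was also taken from the same list, so the step does not decide for this account. The pairs under 1.5 kb, in excess at 500 to 1000 bp and inside the random range at 1000 to 1500 bp, run against that account, which by itself would lower them too; the caller is not given in the sources used here, and a spacing of the binding sites themselves stays open.

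Peaks lay closer together than random placement over whole chromosomes gave, and 3 technical explanations were tested for this. Merging intervals less than 2 kb apart left a ratio of 1.18, above all random placements. A broad region split into several intervals therefore does not account for all of the excess over whole chromosomes. Within 1 Mb bins the merged share, 12.3%, lay below all placements (13.9% to 16.4%, ratio 0.81). Those placements still allowed gaps under 2 kb, which merging had removed from the peaks, so part of this deficit is built in. Taking out all stretches of at least 2.5 Mb without peaks left a ratio of 1.25, again above all placements, which argues against unavailable sequence of that length as the whole cause. Density at the scale of 1 Mb accounted for the share of peaks with a neighbour within 10 kb, but that share includes the scarce distances of 1.5 to 5 kb; pairs 5 to 10 kb apart numbered 935, 1.27 times the mean of placements within 1 Mb bins and above their highest value of 828. Pairs 10 to 15 kb apart numbered 888, also above the highest of those placements, 782. The share within 25 kb, 38.7%, was above their highest value of 36.5% as well. The count of pairs 5 to 10 kb apart replaced a first test on the share within 10 kb. Its lower limit is the step seen in this same list. Pairs are of consecutive peaks, so pairs missing at 1.5 to 5 kb may be counted at longer distances instead. The share within 25 kb takes in the scarce distances. By that share, peaks clustered below the scale of 1 Mb beyond what the density of each bin gives. The cause of that clustering stays open, as do gaps in mappable sequence below 2.5 Mb.

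The list named 172 peaks more than once, 171 of them 2 times and 1 of them 3 times, always in consecutive rows. Repeated peaks had a median width of 1518 bp (quartiles 1171 and 1971 bp), against 864.5 bp for peaks listed once, and none of 100000 random draws of 172 peaks reached that median (permutation p = 1e-05, the smallest the draws can give), which argues against rows repeated without regard to width. The share of repeated peaks rose over the 5 width classes, from 0 of 3320 in the narrowest, which allows up to 0.116% (upper Wilson bound), to 3.74% (3.15% to 4.44%) in the widest. An overlap join could give this rise, with whole intervals of 1 cell type listed once for every interval of the other that they met. In that case the widths and positions come from 1 cell type, and the list does not say which. The rise largely restates that repeated peaks are wide, so it is no separate support for a join. Whether the repeated peaks correspond to 2 neighbouring calls in the other cell type stays open. Their distance to the next peak was 1.03 times that of peaks of like width, inside the range of width-matched draws (0.70 to 1.41). That distance is measured within this list, so it cannot show the calls of the other cell type.

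After the end of the sorted list, the file continued with 16 further rows, of which 13 lay on the chromosomes analysed. Their median width was 566 bp (range 326 to 891 bp), against 868 bp in the sorted part (two-sided permutation p = 0.0041 with 100000 draws). Of the 46 peaks that border the longest stretch without peaks on each chromosome, 3 (6.52%, Wilson 95% interval 2.24% to 17.5%) were wider than 2000 bp, against 2.08% of the others (Fisher's exact test, two-sided, p = 0.0715). These 3 are the peaks already noticed among the 10 widest, so this is no independent test. Of the 173 peaks beside any stretch of at least 2.5 Mb, 2.89% were wider than 2000 bp (p = 0.416 by the same exact test), and their median width was 716 bp, against 869 bp for the others. Beside such stretches that were not the longest of their chromosome, the share was 1.53% (p = 1, exact) and the median width 708 bp.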
